A study of Mus musculus with 2 samples.

How the data were processed

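Thymocytes were taken from Rag1-deficient C57BL/6 mice 4 to 8 weeks old, per the labels' protocols. Chromatin was fixed with 1% formaldehyde for 10 minutes, sonicated and precipitated with an antibody against CTCF. Libraries were made from 10 ng of immunoprecipitated or input DNA, selected on gels at about 200 to 250 bases and amplified for 15 PCR cycles. They were sequenced on an Illumina Genome Analyzer IIx, per the series description. The labels do not say how many animals were pooled or of which sex they were.

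The deposited file is a browser track of the CTCF library. It lists chromosome, start and end, in columns of positions that the authors left without any score, and its header gives only a name and a colour. Per the submitters' processing notes, Bowtie was used and the genome build was mm9. The peak caller, its threshold, the use of the input library and any filter are not given in the sources used here. All 825544 listed intervals were 25 bp long (0 exceptions), and on each of the 22 chromosome names in the file the bins kept a single phase. Only bins within the authors' peaks are listed, so weak binding that their threshold left out cannot be seen. Whether that threshold applied to each bin or to whole peaks is not given. No height, fold or depth can be recovered, and a share of 0 in a stretch does not show that CTCF was absent.

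Bins were joined where they touched, and each run was called a region. Positions were converted from the 0-based track to 1-based coordinates. Width was the distance from the first to the last base of a region. Density was the number of regions divided by the span from the first to the last region of a chromosome, because mm9 chromosome lengths were not used here. Poisson and binomial 95% intervals were exact; the interval of a ratio came from the exact binomial interval of the share of regions in one part. The interval of a mean width was 95% under a normal approximation over regions. Spacing was compared with 100 random placements that kept each chromosome's regions, widths and ends. Placements of joined regions were free to leave gaps shorter than the joining distance. Windows of 1 Mb started at whole Mb, and a region belonged to the window that held its centre. Correlations between windows were compared with 1000 shuffles of windows within chromosomes. With 1 library no test across replicates was possible, and no p-value between conditions is given. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

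The code was tested on simulated data made from the 53548 regions of chromosomes 1 to 19 and X. Regions placed at random were recovered exactly from their bins. Their median gap lay within the range of further random placements (96 of 100 at or below it), whereas regions drawn toward simulated centres lay below all of them (0 of 100).

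The design, the planned part of the alternatives and the rule for named items were fixed before the data were examined. That rule named the 10 highest regions, the chromosomes with the 2 highest and 2 lowest densities, and regions and genes at antigen receptor loci and in fixed gene lists. Since the track holds no heights, the 10 widest regions were named in place of the highest, and width replaced height in the alternatives. The comparison of spacing with random placements was planned. The 1-Mb windows and their correlations, the longest gaps and the change in density along chromosomes were described after the data were seen. So were the maxima and classes of width, the widths on X and width by distance to the nearest region. The gene table supplied for this work follows GRCm38, whereas the submitters' processing notes give mm9 for the track. The last listed position on chromosome 7, 152480204, lies beyond the last gene of that table there, which does not by itself decide the build. Coordinates were not converted. Antigen receptor loci, promoters, the fixed gene lists and the CTCF sequence motif were therefore not analysed here. Apart from this check on chromosome 7, only the chromosome of each gene and whether it is protein-coding were taken from the gene table, for the closing observations.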

Results

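CTCF binding was mapped by ChIP-seq in double-negative (DN) thymocytes of Rag1-deficient C57BL/6 mice. CTCF is a zinc-finger DNA-binding protein found at insulators and at the anchors of chromatin loops. DN thymocytes are T cell precursors that carry neither CD4 nor CD8 on their surface. Cells without RAG1 cannot cut their antigen receptor genes, so they stop at this stage with these genes in germline order. The labels describe 2 libraries, 1 CTCF immunoprecipitate and 1 input control. The values below come from the CTCF library alone, because the input library had 0 processed files in use here. The series title places the map within a survey of CTCF sites in lymphocyte subsets. The other subsets were not analysed here, so the comparisons are between parts of the genome within this library.

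The deposited track listed 825544 bins of 25 bp that its authors reported as CTCF peaks. The bins carried positions only, with no height, score or p-value, so the read depth behind a site is unknown. Each site therefore counted as present or absent, and its width was the sole measure of its size. There was no replicate. All intervals given below cover counting error only, and bound sites that cluster make the true error larger.

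The CTCF-enriched part of the genome was small and broken into many narrow sites. Touching bins formed 53551 regions that covered 20.6 Mb. Of these, 53548 lay on chromosomes 1 to 19 and X, where they took up 0.803% of the span between the first and last region of each chromosome. The mean density was 20.8 regions per Mb. Joining regions separated by up to 200 bp left 47622, and joining across 1000 bp left 44891.

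The distribution of region widths had 3 maxima. The broad class had its most frequent width at 600 bp, with 4662 regions, and 23159 regions measured 500 to 700 bp. That was 43.2% of all regions (exact 95% interval 42.8 to 43.7%), and these regions held 66.2% of the covered length. A narrow class of 100 bp or less held 11958 regions, 22.3% of the total, but 3.18% of the covered length. Its limit was a chosen cut and not a break, since counts fell steadily from 25 bp, the smallest width possible, to 743 at 225 bp. Regions of 125 to 300 bp numbered 8654, or 16.2% of the total. A further, sharp maximum stood at 325 bp, with 2697 regions against 1015 at 300 bp and 1235 at 350 bp. The median width was 425 bp, with quartiles of 125 and 600 bp. The median fell in the trough between classes and rose to 525 bp once regions within 200 bp of each other were joined.

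**Figure D1:**
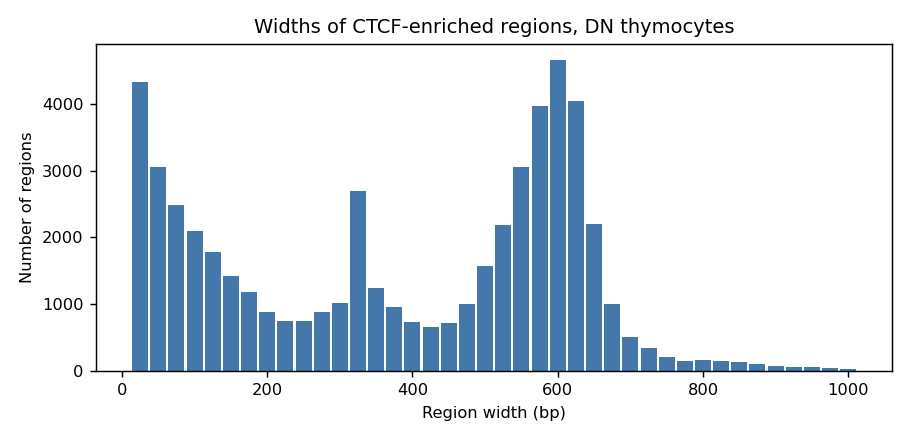
Number of CTCF-enriched regions (y axis) at each width in steps of 25 bp (x axis, up to 1000 bp) on chromosomes 1 to 19 and X. Maxima stand at 25 bp, the smallest width possible (4326 regions), at 325 bp (2697 regions) and at 600 bp (4662 regions).

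Narrow regions often lay beside another region. Of the regions of 100 bp or less, 48.3% (exact 95% interval 47.4 to 49.2%) had a second region within 200 bp, compared with 6.99% (6.66 to 7.32%) of regions of 500 to 700 bp. The remaining 6181 narrow regions had no such neighbour. Very wide regions were rare, and 1795 regions, 3.35% of the total, exceeded 700 bp. The widest spanned 6300 bp on chromosome 17, from 39979702 to 39986001. The next 4 were far narrower. They measured 2050 bp on chromosome 6 (70754371 to 70756420), 2000 bp on chromosome 2 (147003224 to 147005223), 1925 bp on chromosome 4 (132978611 to 132980535) and 1800 bp on chromosome 2 (164618549 to 164620348). Ranks 6 to 10 ran from 1725 down to 1600 bp, on chromosomes 5, 2, 9, 3 and 6. Genes at these positions were not analysed here. The input library was not used, so background signal at the widest regions cannot be told apart from CTCF binding.

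CTCF regions were spread unevenly over the chromosomes. Chromosome 11 had the highest density, 33.9 regions per Mb (exact Poisson 95% interval 32.9 to 35.0) from 4029 regions, followed by chromosome 19 with 27.5 per Mb (26.2 to 28.9). The lowest density of any autosome was 16.3 per Mb (15.7 to 17.0) on chromosome 3, and chromosome 18 came next with 17.3 per Mb (16.5 to 18.2). The highest autosome exceeded the lowest 2.08-fold, and their counting intervals lay far apart.

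Chromosome X stood below every autosome. It held 1294 regions, or 7.96 per Mb (exact Poisson 95% interval 7.53 to 8.40), against 21.7 per Mb over the 19 autosomes together. The ratio of X to autosomes was 0.367 (95% interval 0.347 to 0.388). Against chromosome 3, the sparsest autosome, the ratio was 0.487. The deficit was larger for wide sites, with an X to autosome ratio of 0.312 (0.285 to 0.340) among regions of 500 bp or more. At 600 bp or more, the upper quartile of width, the ratio was 0.203. That cut lies at the most frequent width, and regions of the broad class were narrower on X. The value of 0.203 therefore reflects in part that shift in width, and not only fewer sites.

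**Figure D2:**
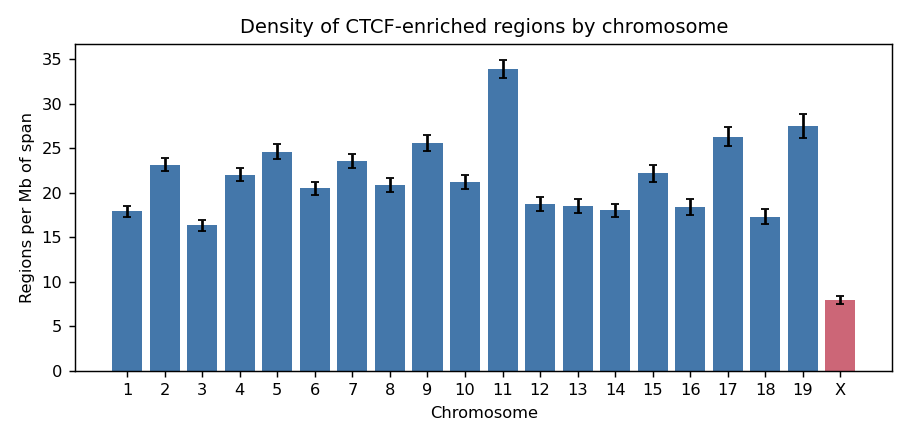
Density of CTCF-enriched regions (y axis, regions per Mb of the span between first and last region) for each chromosome (x axis). Bars are the density in the single library and whiskers its exact Poisson 95% interval; X (7.96 per Mb) lies below the sparsest autosome, chromosome 3 (16.3 per Mb).

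Wide sites on X were fewer and somewhat narrower, while the share of very narrow sites was not raised. The median width was 375 bp on X, as on chromosome 13, and 425 bp on the autosomes together. Regions of 100 bp or less made up 20.87% of X regions, against 20.88 to 24.04% on the autosomes. Regions of 500 bp or more made up 39.7% of X regions (exact 95% interval 37.0 to 42.4%) and 46.8% of autosomal regions (46.3 to 47.2%). The autosomes ranged from 43.5% on chromosome 13 to 50.6% on chromosome 19. Within the broad class of 500 to 700 bp, the mean width was 570 bp on X (95% interval 566 to 574 bp, 496 regions). The lowest autosomal mean was 585 bp on chromosome 3 (582 to 588 bp, 1111 regions) and the highest was 595 bp on chromosome 11 (593 to 597 bp, 1768 regions).

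**Figure D3:**
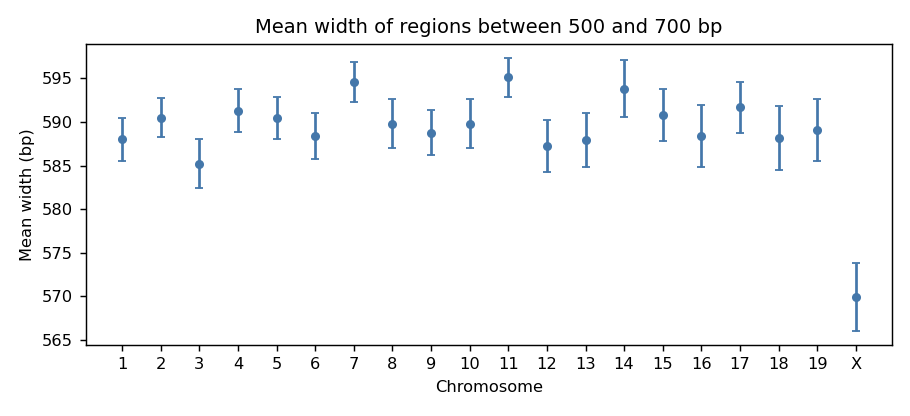
Mean width in bp (y axis, which does not start at 0) of regions between 500 and 700 bp on each chromosome (x axis), with whiskers for the 95% interval of the mean over regions. X, at 570 bp, lies below the autosomes, which range from 585 to 595 bp.

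CTCF regions lay closer together than the same regions placed at random on the same chromosomes. The median gap between neighbours was 14.6 kb, whereas 100 random placements gave 31.3 to 32.0 kb. The excess of short gaps reached beyond the pieces of one site. Gaps over 1 and up to 10 kb made up 25.8% of all gaps, against 17.3 to 18.0% in the placements. With regions joined across 1000 bp, this class made up 30.8% against 14.8 to 15.5%, and the median gap was 20.7 kb against 37.2 to 38.4 kb. Gaps of 10 to 100 kb were correspondingly fewer, 47.8% against 67.6 to 68.5%.

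Long stretches without CTCF regions were present as well. There were 178 gaps over 1 Mb, and the longest gap in any placement was 1.57 Mb. The longest observed gap, 9.10 Mb, lay on X from 23954436 to 33057835. The next was 7.68 Mb on chromosome 7, from 39067430 to 46744229. The following 3, of 5.26, 5.20 and 5.17 Mb, were all on X. Gaps over 1 Mb took up 35.3% of the X span and 10.3% of the autosomal span. Whether these stretches could be mapped at all was not recorded in the track.

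**Figure D4:**
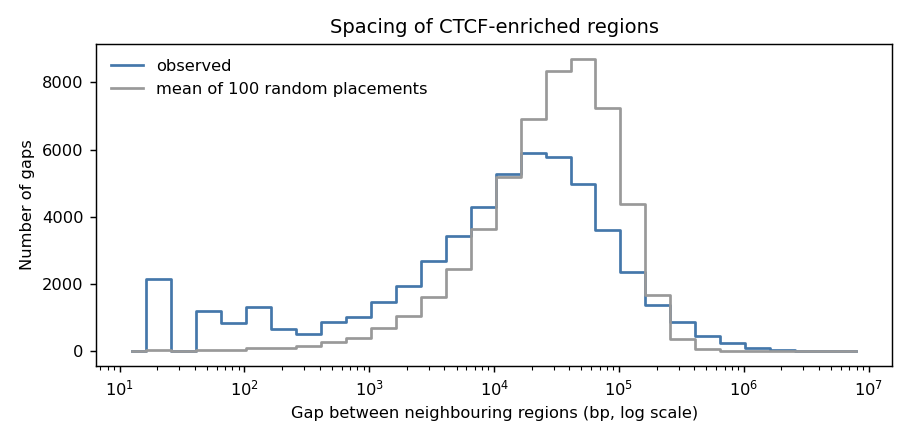
Number of gaps (y axis) by gap length between neighbouring CTCF-enriched regions (x axis, bp, log scale). The blue line is the observed list (median 14.6 kb) and the grey line the mean of 100 random placements of the same regions (medians 31.3 to 32.0 kb).

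At the scale of 1 Mb, CTCF regions were spread more unevenly over windows than in random placements. The 2545 full windows held a median of 16 regions, with quartiles of 6 and 31. Their variance was 16.9 times their mean, against 2.19 to 2.33 times in 100 random placements. The densest 5% of windows held 17.0% of regions, against at most 8.88% in a placement. In 153 windows the count exceeded 55, the highest count in any placement. Of all windows, 132 (5.19%) held no region, and 34 of these were among the 162 windows of X.

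The densest window was at 80 to 81 Mb on chromosome 10, with 110 regions, and the adjoining window at 79 to 80 Mb held 98. Chromosome 17 had 108 regions at 35 to 36 Mb and 96 at 29 to 30 Mb. Chromosome 11 had 102 at 69 to 70 Mb and 89 at 98 to 99 Mb. Chromosome 7 had 96 at 52 to 53 Mb, chromosome 14 had 90 at 53 to 54 Mb, chromosome 3 had 89 at 89 to 90 Mb and chromosome 10 had 88 at 127 to 128 Mb. On X the densest window, at 7 to 8 Mb, held 36. Of the 10 densest windows, 8 were still among the top 10 after regions within 1000 bp were joined, and 5 when only regions at or above the median width of 425 bp were counted.

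The window on chromosome 14 held the largest number of wider sites of all windows. It ranked 7 by all regions and 1 by regions of 425 bp or more, of which it held 68. The first region in it started at 53049695 and the last ended at 53987569. In this window 72.2% of regions were 500 bp or wider (exact 95% interval 61.8 to 81.1%). Among the 23 windows with at least 80 regions, the median share was 48.1% and the highest other share was 60.2%. The neighbouring windows held 40 regions on the side of lower coordinates and 75 on the other. Its share of wider sites was not unique among less dense windows. Of the 1100 windows with at least 20 regions, 9 others had at least its 75.6% of regions at 425 bp or more. This window, and both minimum numbers of regions, were chosen after the values were seen.

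**Figure D5:**
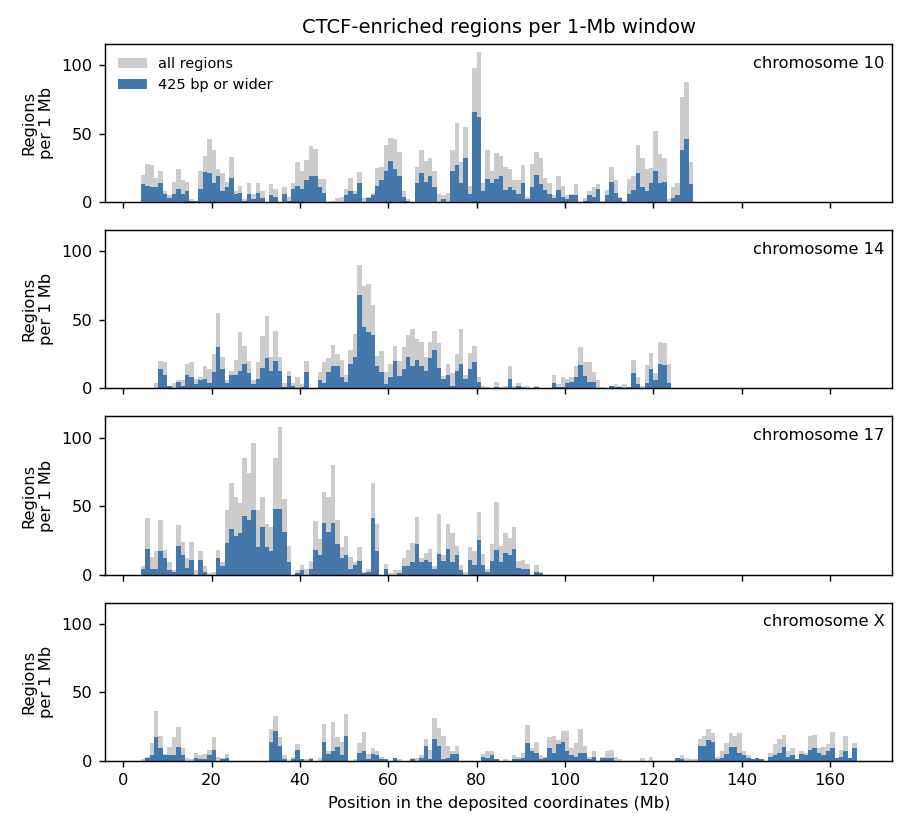
CTCF-enriched regions per 1-Mb window (y axis) along chromosomes 10, 14, 17 and X (x axis, Mb in the deposited coordinates), with all regions in grey and those of 425 bp or more in blue. The window at 53 to 54 Mb on chromosome 14 holds 68 of the wider regions, and the densest window on X holds 36 regions of any width.

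High and low density extended over neighbouring windows. Across windows, the correlation between the counts of adjacent windows was 0.61 (Pearson's r), and it was 0.43 at a distance of 2 Mb, 0.22 at 5 Mb and 0.16 at 10 Mb. In 1000 shuffles of windows within chromosomes the highest r was 0.14 at 1 Mb and 0.14 at 10 Mb. At 20 Mb the observed r of 0.14 lay below the highest shuffled value of 0.15. Windows are not independent replicates, so these values describe this map. Regions also thickened toward the end of the chromosomes with the higher coordinates. The last 10% of the spans held 30.3 regions per Mb and the first 10% held 15.4 per Mb. The last 10% of the span held over 10% of a chromosome's regions on 15 of 20 chromosomes, and the first 10% of the span did so on 3 of 20.

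Isolated CTCF regions were narrower than those with neighbours. For this comparison regions within 200 bp were joined, so that pieces of one site did not count as neighbours. The width of a joined region includes the gaps inside it, so joining itself made those regions wider. Of regions with the nearest other region 1 to 10 kb away, 57.3% (exact 95% interval 56.7 to 58.0%) were 500 bp or wider. At 0.2 to 1 kb the share was no higher, 56.1% (54.7 to 57.5%). At 10 to 100 kb the share was 50.8% (50.1 to 51.5%), and beyond 100 kb it was 32.3% (30.1 to 34.4%). On 20 of 20 chromosomes the share beyond 100 kb lay below the share within 10 kb.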

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

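Width filters, the window results and joining beyond the planned cases were chosen after seeing the data. Of 27 alternative values for 6 results, 11 stayed within the counting interval or within 1.5 times the reported count, 16 moved and 0 changed direction. Region counts, median widths and the ratio of the highest to the lowest autosome have no direction to change. For those results the 0 was fixed in advance. The 53551 regions became 27318 at or above the median width and 14197 at 600 bp or more (the upper quartile of width), by construction. The median width of 425 bp became 525 bp with joining within 200 bp or within 1000 bp, 625 bp at 600 bp or more and 550 bp without regions of 100 bp or less. The X to autosome ratio of 0.367 became 0.335 at or above the median width, 0.203 at 600 bp or more and 0.442 per 1-Mb window that holds a region. The ratio of the highest to the lowest autosome, 2.08, became 2.48 at 600 bp or more. The median gap, as a ratio to that of random placements, was 0.461, and became 0.546 joined within 1000 bp, 0.522 joined within 200 bp, 0.481 at or above the median width and 0.442 at 600 bp or more. The variance of window counts over their mean, 16.9, became 13.0 joined within 1000 bp and 10.1 at or above the median width. Beyond the effect of fewer or longer regions, the cause was not tested. Alternatives by peak height, by chromosome length, at antigen receptor loci, at start sites, in gene lists and for the motif were not run, for want of heights, mm9 lengths and mm9 genes. No paired analysis was possible because there was 1 library. Depth is unknown, so it is open how many weaker sites the threshold left out.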

Other observations

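All tests here were chosen after the data were seen. For these observations the gene table of the GRCm38 build gave only the chromosome of each gene and whether it is protein-coding. Autosomes with more protein-coding genes had more CTCF regions: across the 19 autosomes Pearson's r between genes per Mb and regions per Mb was 0.87 and Spearman's rho 0.90, each with a permutation p of 1e-05, the smallest that 100000 permutations can give (two-sided; adjusted by Benjamini-Hochberg over 4 relations, 1.33e-05 and 1e-05). Without the 2 chromosomes farthest from the median gene density r was 0.93. Both densities share the span as denominator, so the test was repeated on log numbers after removing log span, which gave r = 0.89 with the same p. Chromosome 7 had the fewest regions per gene of the autosomes, 1.74 against 2.53 over all autosomes. The hypothesis that CTCF regions follow gene density is consistent with these values, at the scale of whole chromosomes only. Chromosomes are not replicates.

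Among the chromosomes that carry antigen receptor genes, chromosome 14 carries Tcra and Tcrd, which encode the alpha and delta chains of the T cell receptor. Its window at 53 to 54 Mb held more regions of 425 bp or more (68) than any other 1-Mb window in the map. On chromosome 12, which carries the immunoglobulin heavy chain locus Igh, the densest window for such regions was at 116 to 117 Mb, with 44 and rank 19. On chromosome 6, which carries Tcrb and Igk, it was at 124 to 125 Mb with 36 and rank 81. On chromosome 16, which carries Igl, it was at 17 to 18 Mb with 38 and rank 57, and on chromosome 13, which carries Tcrg, at 55 to 56 Mb with 28 and rank 179. Each of these windows was picked as the maximum of its chromosome, not by the position of a gene. Their counts and ranks therefore cannot be read as values of a receptor locus. Chromosomes outside this group also ranked high. Chromosome 10 had windows with 66 and 62 such regions (ranks 2 and 3), and chromosome 11 had windows with 52 and 50 (ranks 4 and 5). Whether any of the windows on the receptor chromosomes holds the receptor genes was not tested, because no mm9 gene positions were used.

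For the low density on X, fewer genes as the whole cause is argued against, since X still had 0.530 times the autosomal number of regions per protein-coding gene (95% interval 0.501 to 0.560), and its 1.34 regions per gene lay below the autosomal range of 1.74 to 3.26. In 1-Mb windows that held a region the ratio was still 0.442, so windows without any region were not the whole cause. A window with 1 region can still hold stretches in which nothing could be called. Such stretches therefore stay open as a cause. Weaker signal at sites on X, as a single copy in males would give, stays open. The mean width of 570 bp (569.9) within the broad class lay below that of every autosome. The X to autosome ratio fell from 0.367 over all regions to 0.312 at 500 bp or more and 0.203 at 600 bp or more. This fall is not separate from the lower mean width, since narrower regions also lower the ratio above a width cut. The share of regions of 100 bp or less (20.87%) was not above the autosomal range of 20.88 to 24.04%. That share cannot decide the question, because weak sites can have been left out of the list altogether. Near other regions (200 bp to 10 kb) 45.6% of X regions were 500 bp or wider (exact 95% interval 40.9 to 50.4%) against 57.3% (56.7 to 57.9%) on autosomes. At 10 to 100 kb the shares were 46.9% (42.9 to 50.9%) and 51.0% (50.2 to 51.7%). Beyond 100 kb, with 133 regions on X, they were 33.8% (25.9 to 42.5%) and 32.1% (30.0 to 34.4%). At these 2 distances the intervals overlapped, which does not show that the shares were equal. The sex of the animals, mappability and a true scarcity of CTCF sites on X stay open.

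The maximum at exactly 325 bp was present on 20 of 20 chromosomes, where this width was 1.85 to 3.30 times as frequent as the mean of 300 and 350 bp. Among regions over 10 kb from any other the excess was still 2.45 times, so pieces lying beside other listed regions are not its whole source. Pieces of wider stretches stay open, since the rest of a stretch can have fallen below the authors' threshold. The peak caller is not known here, so a length set by the peak calling stays open and was not tested, and no biological explanation was tested.

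Regions of 100 bp or less may in part be pieces of wider enriched stretches, as 48.3% of them had another region within 200 bp, against 6.99% of regions of 500 to 700 bp. The other 6181 had none that close, and 3065 of these lay over 10 kb from any region. For these the explanation stays open, since the rest of a stretch can have fallen below the authors' threshold. Weak sites that barely passed the threshold stay open as a source too, and no biological explanation was tested.

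Outside the nuclear comparisons, the mitochondrial chromosome held 10 listed bins in 2 regions, of 200 bp from 11002 to 11201 and of 50 bp from 12402 to 12451. Chromosome Y held 1 bin, from 2765777 to 2765801. The input library was not used here, so no background stands beside these values.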
